A study of Mus musculus with 14 samples.

How the data were processed

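The series holds 14 mouse samples of 2 kinds. RNA-seq was made from 8 primary hippocampal cultures, prepared from pups of postnatal day 0 to 1 and kept for 14 days in vitro. Of these, 4 received 0.1% DMSO, the solvent, for 15 h (group CTRL) and 4 received 100 µM picrotoxin for 15 h (group PTX). Picrotoxin blocks GABA-A receptors, the main inhibitory ion channels of the brain, and so raises network activity. ChIP-seq with an antibody against L3mbtl1, a chromatin reader with MBT domains, was made from hippocampus of postnatal day 7 to 8. It has 3 samples of wild-type and 3 of L3mbtl1 knockout mice. Groups and replicate numbers were taken from the sample titles.

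The RNA-seq values were raw read counts per Ensembl gene as deposited by the authors, with 1 table per library. Per the labels' protocols, total RNA was depleted of ribosomal RNA and 15 ng entered a ScriptSeq v2 library. Per the submitters' processing notes, CASAVA 1.8, TopHat2 2.0.9, HTSeq 0.6.1 and Bowtie2 2.2.4 were used, with genome build mm10. The notes used here give no roles, and the strand setting of the counting and the annotation release are not given in the sources used here. Reads of a gene and of its antisense partner or an overlapping gene therefore cannot be told apart, and genes with near-identical copies are uncertain. Each count table listed 43629 gene identifiers, of which 42462 matched a symbol, 1167 did not and 40 shared a symbol with another identifier. The 5 summary lines at the end of each table were kept out of library sizes and tests. They put 19.9% to 26.8% of counted alignments outside any gene and 15.2% to 20.5% at non-unique positions. Gene counts per library ran from 14524916 to 19498189. At this depth 22513 to 23535 genes had at least 1 count. No library was a copy of another, since the smallest chi-square per degree of freedom between libraries of 1 group was 10.3.

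The ChIP-seq values were a list of 4677 peaks with a score per peak, as deposited by the authors for all 6 ChIP-seq samples together. The list is described as the outcome of IDR, a filter on the reproducibility of peaks between replicates. The peak caller, the IDR threshold, the meaning of the score, the pooling of replicates and the use of the knockout samples are not given in the sources used here. The score is the authors' own and was used only to rank and filter peaks within the list and in 1 test on the X chromosome. Wild-type and knockout signal were not compared, since no table per ChIP-seq sample was analysed here.

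PTX and CTRL counts were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, group as the only term) in R 4.3.3. Benjamini-Hochberg adjusted p under 0.05 over the 15959 tested genes counted as a call. CPM values were computed on TMM-scaled library sizes, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. The direction of 31 gene lists, each with at least 3 tested members, was tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. fry, which asks whether a list's genes move one way on balance without comparing them with other genes, was run beside it. The words rose and fell are used of genes past the threshold over all tested genes. For genes with 0 counts in a group, a floor of 3 counts over the group, close to the 1-sided 95% limit of a count of 0, gave the bound. For genes with 1 to 3 counts in a group, the ratio is given with its 95% exact binomial interval. These bounds and intervals cover counting error only.

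The gene lists, the tests and the rule for named genes were fixed before the data were examined, apart from those said to be added later. The rule takes L3mbtl1, Ctnnb1 and Gabra2, the 10 largest rises and 10 largest falls among called genes with a symbol, a mean CPM of at least 1 and groups that do not overlap, the 3 members of each list with the smallest p, the 10 peaks of highest score, and peaks of genes named by the other parts. Other members of a list are named where a count of 5 or fewer or an exception would otherwise stay unnamed, and these names were chosen after their values were seen. Values of some members of the lists are not reported here. A list of 10 keratinocyte genes was written after their counts had been seen.

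The planned peak analysis used transcription start sites. The annotation used here (RefSeq, GRCm38.p6, the assembly of mm10) was a table of gene positions without strand, so the start of a gene could not be told from its end. Peaks were instead set against windows of 2000 bp on each side of both ends of each gene, with an overlap of at least 1 bp. The share of peaks near an end of a protein-coding gene was compared with 100 seeded shuffles of the peaks within chromosomes. Of the tested genes, 14729 (92.3%) had a position. Peaks and PTX calls were compared with a 2-sided Fisher's exact test, and genes are not independent replicates. Exon, intron and UTR positions were not used here.

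Replicate numbers run from 1 to 4 in both RNA-seq groups. Deviations from the group means over 12318 expressed genes correlated between same-numbered libraries with r = 0.83, 0.663, 0.262 and 0.755 for numbers 1 to 4, across genes, and 7 of 8 libraries were closest to their own number in the other group. The exception was CTRL replicate 3, which was closest to PTX replicate 4 (r = 0.308). The numbers were therefore read as pairing the libraries, on the evidence of these counts and not of the labels. The main fit nevertheless had group as its only term, so calls ignore the pairing unless the block is named. A fit with the replicate number as a block is given where it changed the call of a named gene or moved a list's count of called members by over 1.5 times.

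Alternatives were RLE scaling, no low count filter, DESeq2 1.42.0, limma-voom, the replicate block, leaving out each library, camera with a correlation estimated per list, windows of 1000 and 5000 bp, the peak centre, the 2338 peaks of higher score, DESeq2 calls, and a comparison within 10 bins of mean expression, made by logistic regression with the bins as terms. Leaving out both libraries numbered 1 or both numbered 2, and the block together with an estimated correlation, were added after the data were examined. The steps were tested on simulated data. Counts were drawn for the 15959 tested genes, of which 15871 passed the filter, with the changed genes taken from those above 1 log2 CPM. From these edgeR recovered 32.8% of 67 genes changed 1.5-fold, 77.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. Of its 149 calls, 10 were unchanged genes. Camera called the planted list and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other, so this does not test camera where the genes of a list are correlated. The peak step found 100.0% of planted peaks. Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6 were used.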

Results

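The RNA-seq libraries measured steady-state transcripts of mouse hippocampal cultures after 15 h of picrotoxin (PTX, n = 4) or of its solvent DMSO (CTRL, n = 4). The ChIP-seq assay gave 1 list of 4677 genomic positions assigned to L3mbtl1 in hippocampus. The first comparison asks which transcripts change when inhibition is blocked, with L3mbtl1 itself first. The second asks where L3mbtl1 peaks lie, and the third whether genes that change with activity carry such peaks.

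L3mbtl1 (ENSMUSG00000035576, mm10 chromosome 2, 162942333 to 162977806) fell under picrotoxin. Its level was 9.97 ± 0.97 CPM in CTRL and 2.92 ± 1.83 CPM in PTX (SD, n = 4 each), a 3.39-fold fall (fell by 1.76 on the log2 scale, SE 0.34, edgeR adjusted p = 0.00249). It was lower in PTX in 4 of 4 same-numbered pairs. The PTX library numbered 2 kept the most, with 5.6 CPM against 1.52 to 2.36 CPM in the other PTX libraries. Ctnnb1 (ENSMUSG00000006932, beta-catenin, an adhesion and Wnt pathway protein, chromosome 9, 120933400 to 120960507) was at 1075 ± 47.6 CPM in CTRL and 965.6 ± 73.4 CPM in PTX, which did not pass the test (edgeR adjusted p = 0.178). Gabra2 (ENSMUSG00000000560, a GABA-A receptor subunit, chromosome 5, 70958392 to 71095849) was at 145 ± 69.7 CPM in CTRL and 236.1 ± 87.8 CPM in PTX. It did not pass the test without pairing (log2 fold change 0.70, SE 0.35, edgeR adjusted p = 0.146). It was higher in PTX in 4 of 4 pairs and passed with the replicate block (edgeR adjusted p = 1.53e-05). Without CTRL replicate 1 it also passed, with a log2 fold change of 1.09 and edgeR adjusted p = 0.0291. Over its alternatives adjusted p ran from 1.53e-05 to 0.3.

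**Figure D1:**
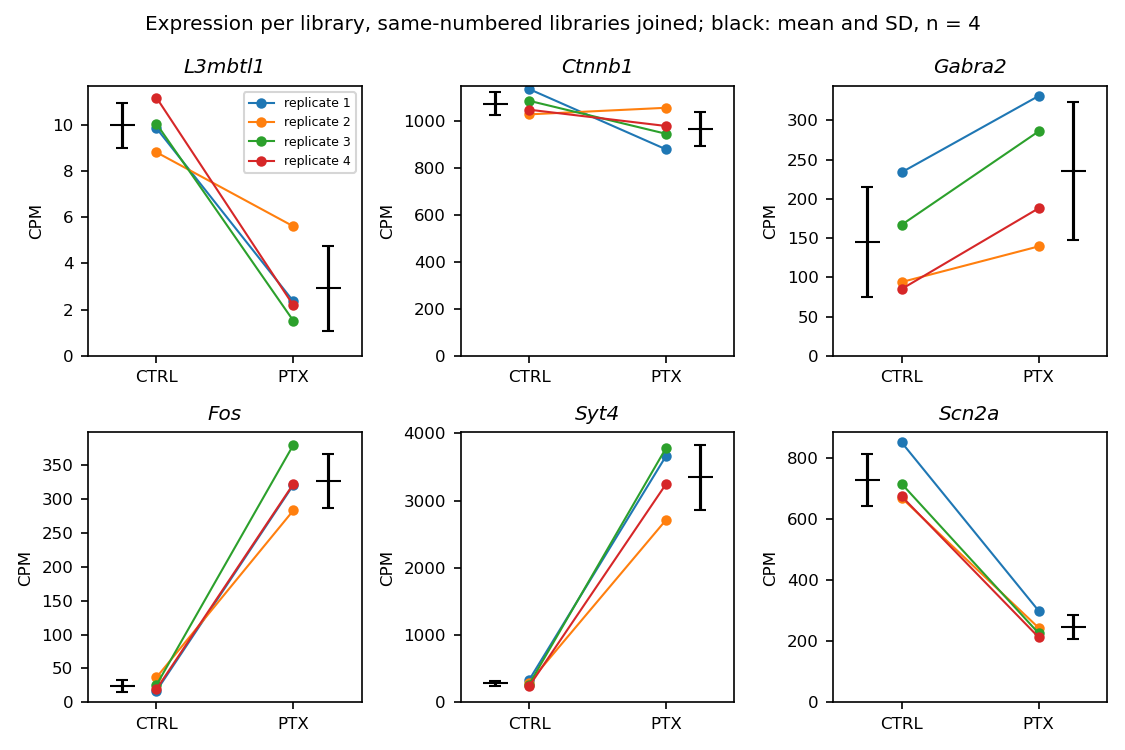
CPM (vertical axis, from 0) of 6 genes in the 4 CTRL and 4 PTX libraries. Coloured lines join libraries of the same replicate number, and black bars give mean and SD. L3mbtl1 and Scn2a were lower and Fos, Syt4 and Gabra2 higher in PTX in 4 of 4 pairs, and the libraries of 1 group differed in Gabra2 by more than the group means did.

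Picrotoxin changed 6248 of 15959 tested genes (39.2%), of which 3034 rose and 3214 fell (edgeR adjusted p under 0.05). At least 2-fold changes made up 1896 of these, with 1078 higher and 818 lower. Counts of called members in the gene lists below, rises and falls together, are to be read against the 39.2%, near which a count is not particular to a list. Rises alone are to be read against 3034 of 15959 and falls alone against 3214 of 15959. These shares are not adjusted for expression level. The first principal component held 60.4% of the variance and parted the CTRL from the PTX libraries. The second held 21% and set both libraries numbered 1 apart from the other 6. In those 2 libraries the meningeal fibroblast markers were high (median log2 CPM 2.36 and 2.22 above the mean of all libraries) and the microglia markers low (-1.84 in CTRL and -1.50 in PTX).

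The largest rises came from genes that were close to silent in CTRL. Krt6a, an epithelial keratin, had 18 counts over the CTRL libraries and 17314 over the PTX libraries (0.26 ± 0.08 and 276.9 ± 118.6 CPM, SD, n = 4, edgeR adjusted p = 6.61e-07). Serpinb2, a protease inhibitor, rose from 0.46 ± 0.43 to 252.5 ± 98.0 CPM. Other rises came from the cornified envelope genes Lce1g (648.4-fold), Crct1 (3 counts in CTRL and 1855 in PTX, ratio 682, interval 233 to 3310) and Lce3c (at least 76.1-fold higher). Ifi214, an interferon-inducible gene, had 2 and 1077 counts (ratio 594, interval 164 to 4910) and the gene model Gm18445 had 3 and 1641 counts (ratio 603, interval 206 to 2930). Igkc, the immunoglobulin kappa constant region, had 0 counts in CTRL and 393 in PTX, at least 144-fold higher. The odorant receptor gene Olfr683 was at least 95.5-fold and the glucuronosyltransferase gene Ugt2b37 at least 50-fold higher. Krt6a, the Lce genes, Ifi214, Igkc, Olfr683 and Ugt2b37 belong to families with similar copies, so the assignment of their reads is uncertain.

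The largest falls included receptor genes. Gpr12, an orphan receptor, fell 12.6-fold from 23.2 ± 3.68 to 1.84 ± 0.28 CPM (SD, n = 4, edgeR adjusted p = 6.45e-07). The neurotensin receptor gene Ntsr1 fell 10.5-fold, the delta opioid receptor gene Oprd1 9.69-fold and the small GTPase gene Rasl10a 9.19-fold. Cxcl5, a chemokine, fell 29.9-fold from 16.2 ± 11.9 CPM, a level that varied widely between CTRL libraries. The gene models Gm17322 (32.6-fold), Gm4810 (24.8-fold), E030013I19Rik (16.2-fold), Gm37711 (10.0-fold) and 4930539E08Rik (9.29-fold) completed the 10 largest falls.

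Most members of the 2 lists of genes known to respond to neuronal activity rose. Of 22 immediate early genes, which are transcribed within minutes of activity without new protein, 18 rose and 1 fell. Fosb rose 66.0-fold (0.66 ± 0.35 to 44.5 ± 10.2 CPM, SD, n = 4), Fos 13.2-fold and Fosl2 6.36-fold, all encoding AP-1 subunits. The 1 that fell was Egr3 (2.76-fold, edgeR adjusted p = 0.00106), while Egr2 rose 6.04-fold and Egr1 1.31-fold. Of 30 delayed activity-response genes, 29 rose and 0 fell, with Rasgrp1 the 1 that did not pass (edgeR adjusted p = 0.0512) and the 1 that fell with the replicate block. Ptgs2, encoding cyclooxygenase 2, rose 167.1-fold, Inhba, encoding the activin A subunit, 121.3-fold, and the synaptotagmin gene Syt4 11.9-fold to 3349 ± 483.2 CPM (SD, n = 4). Counts adjusted over the list alone were 19 up and 1 down for immediate early genes and 29 up and 1 down for delayed genes. Both lists moved up against other genes (camera adjusted p = 2.69e-19 and 2.82e-56). With an estimated correlation the delayed list kept its call (adjusted p = 0.0343) and the immediate early list lost it (adjusted p = 0.183). With the replicate block and an estimated correlation the delayed list lost its call too (adjusted p = 0.235, the highest over its alternatives).

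Of 23 neuropeptide and granin genes, 16 rose and 1 fell (with the replicate block 3 fell, Nxph1, Scg5 and Tac2). Adcyap1, encoding PACAP, rose 17.9-fold to 423.2 ± 82.8 CPM (SD, n = 4), Scg2, encoding secretogranin II, 12.9-fold to 2924 ± 316 CPM, and Pnoc, encoding nociceptin, 9.81-fold. The 1 that fell was Nxph1, encoding a neurexin ligand. The list moved up (camera adjusted p = 6.66e-11, adjusted p = 0.215 with an estimated correlation). Of 20 genes of the unfolded protein response and chaperones, 15 rose and 1, Pdia4, fell. Sdf2l1 rose 8.72-fold, the chaperone gene Hspa5 2.1-fold from 690 ± 28.1 to 1446 ± 81.2 CPM (SD, n = 4) and its regulator Xbp1 2.07-fold (camera adjusted p = 1e-06, adjusted p = 0.296 with an estimated correlation). Of 16 glycolysis genes, 10 rose and 1, Pfkm, fell (with the replicate block Eno2 fell too). Hk2 rose 3.36-fold, Pgk1 1.84-fold and Gapdh 1.41-fold. The list passed camera with adjusted p = 0.0219, and adjusted p = 0.621 with an estimated correlation. Adjusted over the list alone, the counts were 17 up and 3 down for neuropeptides and 17 up and 1 down for chaperones.

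In the 4 glutamate receptor lists more members fell than rose. Of 9 AMPA and kainate receptor subunits, which carry fast excitatory transmission, 7 fell and 0 rose (with the replicate block Grik4 rose and 8 fell, and 8 fell adjusted over the list alone). Grik2 fell 1.86-fold, Gria4 1.54-fold and Gria3 1.48-fold. The list passed camera (adjusted p = 0.0219, adjusted p = 0.552 with an estimated correlation) and missed it without CTRL replicate 1 (camera adjusted p = 0.0545, range over alternatives 0.000981 to 0.552). Of 7 metabotropic receptors, 5 fell, among them Grm5 (3.51-fold) and Grm3, and Grm7 (1.66-fold) and Grm8 rose. Grm5 went from 409.3 ± 83.6 to 116.7 ± 18.2 CPM (SD, n = 4). This list passed camera (adjusted p = 0.017), with adjusted p = 0.451 under an estimated correlation. Of 12 auxiliary subunits of AMPA receptors, 7 fell, among them Gsg1l (2.65-fold), Shisa7 (by 0.85 on the log2 scale) and Cpt1c (1.46-fold), and 1, Cacng3, rose, but the list missed the camera threshold (adjusted p = 0.0612). It passed without CTRL replicate 4 (camera adjusted p = 0.0495) and without PTX replicate 1 (0.0243), over a range of 0.00669 to 0.607 across its alternatives. Of 6 NMDA receptor subunits, Grin3a (1.52-fold), Grin2b and Grin2d fell and 0 rose (with the replicate block Grin2c rose and Grin2a fell too, and Grin2c rose adjusted over the list alone, camera adjusted p = 0.423). The calls of Grin2b and Grin2d were each lost without CTRL replicate 1, 3 or 4 or PTX replicate 2, 3 or 4. Over alternatives edgeR adjusted p ran from 3.67e-05 to 0.18 for Grin2b and from 0.00767 to 0.106 for Grin2d.

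In the 3 lists of voltage-gated channels more members fell than rose. Of 27 potassium channel genes, 16 fell and 5 rose (17 and 5 adjusted over the list alone). Kcnip2 fell 7.81-fold and Kcnb2 3.73-fold, whereas Kcna4, Kcnf1, Kcna1, Kcnh1 and Kcnd2 rose (camera adjusted p = 5.18e-05, adjusted p = 0.369 with an estimated correlation). Of 7 sodium channel genes, 5 fell and 0 rose (6 fell adjusted over the list alone). Scn2a fell 2.96-fold from 726.5 ± 84.7 to 245.9 ± 38.1 CPM (SD, n = 4), Scn2b 2.68-fold and Scn3b 2.27-fold, and Scn3a and Scn8a were the others (camera adjusted p = 0.000178, adjusted p = 0.451 with an estimated correlation). Of 15 calcium channel genes, 8 fell, with Cacnb3 2.98-fold, Cacna1d 2.75-fold and Cacna2d3 1.66-fold lower, and Cacna1e and Cacnb4 rose. The list passed camera with adjusted p = 0.0136, had adjusted p = 0.621 with an estimated correlation and missed the threshold without PTX replicate 2 (camera adjusted p = 0.0578, range over alternatives 0.000307 to 0.621).

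Other synaptic genes moved both ways. Of 14 GABA-A receptor subunits, 5 fell, among them Gabra4 (1.91-fold), Gabra5 and Gabra3, and 2 rose, among them Gabrq, with camera adjusted p = 0.272. Of 25 postsynaptic density genes, 10 fell and 5 rose (6 rose adjusted over the list alone, camera adjusted p = 0.423). Homer2 fell 2.43-fold and the adhesion gene Nlgn3 1.99-fold, and Dlg1, encoding SAP97, rose 2.03-fold, with Homer1, Dlgap2, Dlgap3 and Lrrtm1 the other rises. Of 20 vesicle release genes, Syt1 (1.63-fold), Rab3a (1.68-fold), Syn2, Cplx2 and Sv2a fell and Snap25 (1.52-fold) and Vamp2 rose (camera adjusted p = 0.276). Of 27 regulators linked to synaptic scaling, 12 rose and 7 fell (13 rose adjusted over the list alone). Arc rose 13.6-fold and the kinase gene Plk2 5.92-fold, and Epha4 fell 2.33-fold. This list passed camera upwards (adjusted p = 0.0152, adjusted p = 0.552 with an estimated correlation), with a median log2 fold change of 0.14 and a mean of 0.70, and Nptx2, Bdnf, Arc, Plk2 and Itgb3 rose most.

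Among 10 MBT-domain chromatin readers, the family of L3mbtl1, 7 fell and 2 rose. L3mbtl1 fell most and Sfmbt2 rose 4.82-fold (9.5 ± 0.74 to 45.8 ± 13.9 CPM, SD, n = 4), with Sfmbt1 1.86-fold higher and L3mbtl3 not past the test (edgeR adjusted p = 0.527, list camera adjusted p = 0.533). Of 30 histone and DNA modifier genes, 11 rose and 6 fell (12 rose adjusted over the list alone, camera adjusted p = 0.273), with the demethylation enzyme gene Tet3 2.64-fold, the deacetylase gene Hdac9 2.49-fold and the methyltransferase gene Dnmt1 1.82-fold higher. Of 21 cadherin and catenin genes, Cdh8 (2.88-fold), Ctnna2 (1.76-fold), Cdh18, Cdh12 and Cdh11 fell and Cdh6 (2.86-fold) and Cdh4 rose (camera adjusted p = 0.268). Of 22 cholesterol biosynthesis genes, 3 rose (Pmvk 3.68-fold, Hsd17b7 1.86-fold and Ebp) and 3 fell (Fdps 2.08-fold, Tm7sf2 and Mvk), against 6 and 12 with the replicate block (3 and 2 adjusted over the list alone, camera adjusted p = 0.901). The Fdps call was lost without PTX replicate 3 (edgeR adjusted p = 0.0546, range over alternatives 4.55e-07 to 0.0599) and without both libraries numbered 2 (0.0599). Of 44 cytosolic ribosomal protein genes, Rpl4 (1.33-fold), Rps3 (1.36-fold), Rpl18, Rps6 and Rpl8 rose and Rpl15 (1.31-fold) fell, against 12 and 1 with the replicate block (1 and 1 adjusted over the list alone, camera adjusted p = 0.272). Without CTRL replicate 3 the Rps3 call was lost (edgeR adjusted p = 0.0505, range over alternatives 0.000505 to 0.0505).

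Markers of several cell types moved with picrotoxin, beside the receptor and channel genes above. Of 12 excitatory neuron markers, 8 fell, among them Neurod2 (3.08-fold) and Camk2a (2.18-fold), and 2 rose, Fezf2 and Slc17a6. Slc17a6, encoding the vesicular glutamate transporter VGLUT2, rose 12.7-fold from 39.4 ± 6.12 to 501.2 ± 91.2 CPM (SD, n = 4), while Slc17a7, encoding VGLUT1, fell 1.57-fold (list camera adjusted p = 0.261). Of 16 inhibitory neuron markers, Gad2 (1.84-fold), Sst (2.15-fold), Gad1, Npy and Vip rose and 5 fell, among them Dlx1 (2.38-fold), Lhx6 and Erbb4 (camera adjusted p = 0.861). Of 15 astrocyte markers, 6 fell, among them Aldoc (2.62-fold) and Aqp4 (2.42-fold) with Slc4a4 (1.59-fold), and Fgfr3 rose. With the replicate block 11 fell. The astrocyte list passed camera (adjusted p = 0.0245, adjusted p = 0.552 with an estimated correlation).

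Of 14 microglia markers, Cd68 rose 3.18-fold and 0 fell (with the replicate block Csf1r and P2ry12 rose too, camera adjusted p = 0.533). P2ry12 had edgeR adjusted p = 0.21 without pairing and 0.0429 to 0.398 over alternatives, and Aif1 did not pass (edgeR adjusted p = 0.39). Of 7 oligodendrocyte markers 0 were called, and Cnp, Cldn11 and Mbp rose with the replicate block (camera adjusted p = 0.749). Cnp and Cldn11 also passed without PTX replicate 1, with edgeR adjusted p over alternatives of 0.000473 to 0.269 and 0.0289 to 0.398. Of 9 oligodendrocyte precursor markers, Vcan rose, a call lost without CTRL replicate 2, 3 or 4 or PTX replicate 3 (edgeR adjusted p over alternatives 0.000998 to 0.0859) and not made adjusted over the list alone, where 0 were called. With the replicate block Vcan, Olig2, Gpr17, C1ql1 and Pdgfra rose, and camera gave adjusted p = 0.533. Olig2 also passed without PTX replicate 1 (edgeR adjusted p over alternatives 0.000429 to 0.319, and 0.000127 to 0.487 for Gpr17). Of 7 endothelial and mural markers, Abcb1a (4.97-fold) and Flt1 (2.76-fold) rose, and with the replicate block Pecam1 rose too (edgeR adjusted p over alternatives 0.0484 to 0.252) and Kdr and Slco1a4 fell. This list's median log2 fold change (-0.02) and its mean (0.42) differed in sign (camera adjusted p = 0.568). Of 11 meningeal fibroblast markers, Fn1 rose 2.28-fold and 0 fell. With the replicate block Dcn, Igf2, Ogn and Slc6a13 fell. Ogn also passed without CTRL replicate 1, and edgeR adjusted p over alternatives ran from 1.53e-05 to 0.368 for Ogn and from 9.75e-05 to 0.852 for Slc6a13, whose log2 fold change was 1.01 without CTRL replicate 1. Camera, which pointed up with adjusted p = 0.901, differed in sign from the list's median of -0.23 and mean of -0.12. Of 20 proliferation markers, Aurka (1.32-fold) and Mcm2 (1.31-fold) rose over all genes and 0 were called adjusted over the list alone (camera adjusted p = 0.901). The Aurka call was lost without any 1 CTRL library or PTX replicate 3 and the Mcm2 call without CTRL replicate 2 or 4 or PTX replicate 2, with edgeR adjusted p over alternatives of 0.0126 to 0.109 and 0.00331 to 0.136. Of 11 mitochondrially encoded mRNAs, mt-Nd1, mt-Nd2 and mt-Atp8 fell 1.35-fold to 1.4-fold, against 8 with the replicate block and 5 adjusted over the list alone (camera adjusted p = 0.167). Each of these 3 calls was lost without CTRL replicate 1. That of mt-Nd1 was lost also without PTX replicate 4, that of mt-Nd2 without CTRL replicate 3 or PTX replicate 3, and that of mt-Atp8 without any library but PTX replicate 1, with edgeR adjusted p over alternatives up to 0.0622, 0.0807 and 0.2. Genes of the mitochondrial genome, its RNA genes other than mRNAs included, held 1.81% ± 0.1 of gene counts in CTRL and 1.6% ± 0.07 in PTX (SD, n = 4).

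**Figure D2:**
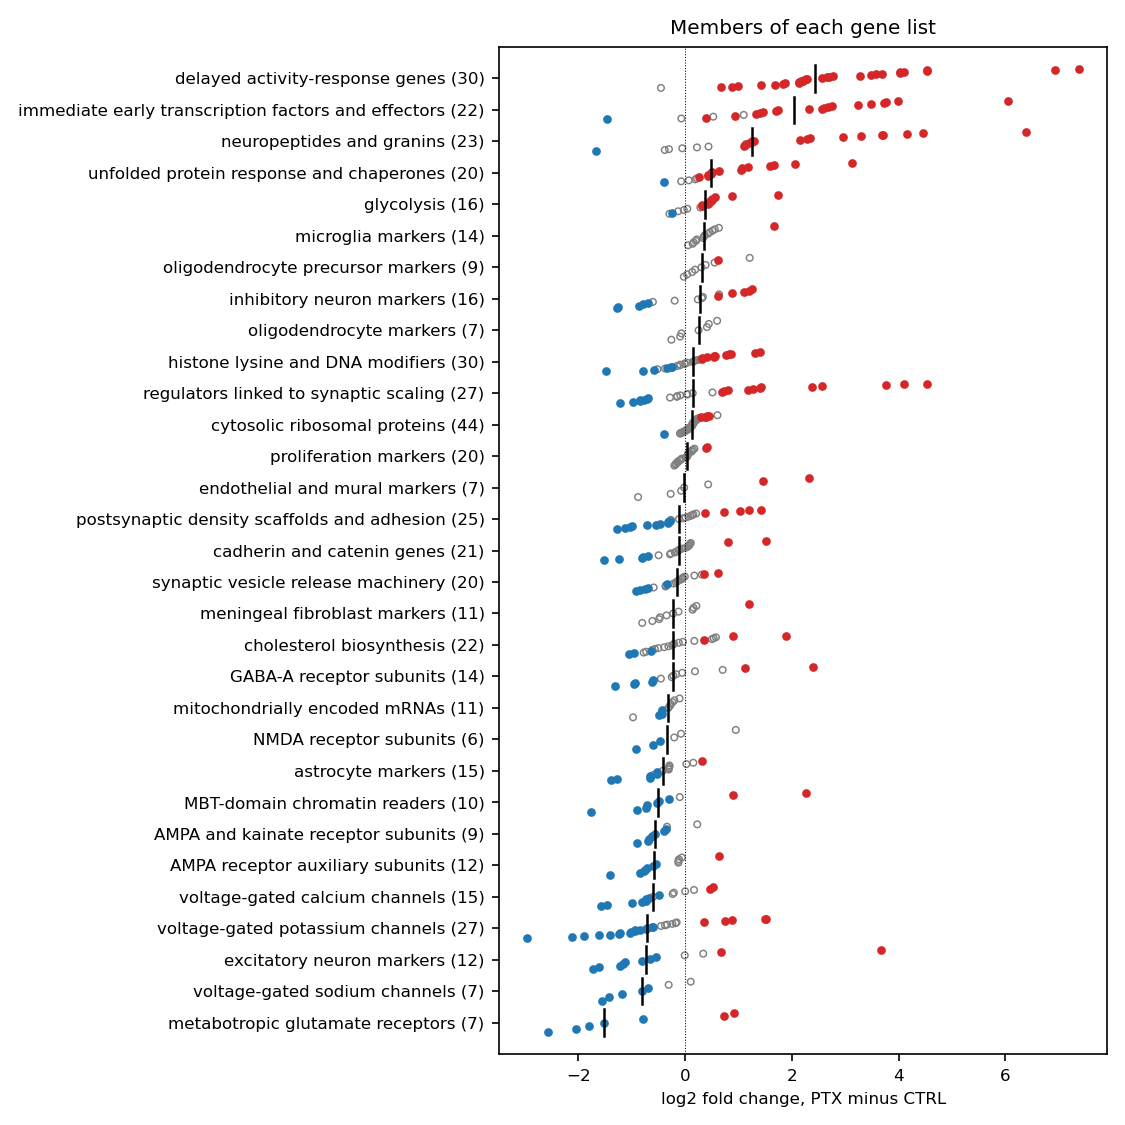
Log2 fold change (PTX minus CTRL, horizontal axis) of every tested member of the 31 gene lists, with the number tested in brackets. Red points rose and blue points fell (edgeR adjusted p under 0.05), open points did not pass, and black bars are list medians, which ran from -1.51 for metabotropic glutamate receptors to 2.42 for delayed activity-response genes.

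In all, 12 of the 31 lists passed camera, 6 upwards and 6 downwards, and 1 of them, the delayed activity-response genes, kept its call with an estimated correlation, but not with that and the replicate block. fry called 20 lists. Counts adjusted over the list alone were given above where they differed from the counts over all genes and were otherwise the same. The real groups gave 12 lists, and other splits of the 8 libraries with 2 CTRL and 2 PTX libraries on each side gave up to 14, so that the number of camera calls alone is weak evidence. Among splits that part all 4 same-numbered pairs the highest other was 11.

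The L3mbtl1 peaks lay close to the ends of genes. Of 4677 peaks, 3962 (84.7%, Wilson 95% interval 83.7% to 85.7%) came within 2000 bp of an end of a protein-coding gene, against 6.94% on average and 7.78% at most in 100 shuffles within chromosomes. The share at a start site was not analysed here. Peaks were 165 to 8215 bp wide, with a median of 747 bp, and covered 4.11 Mb. Their scores ran from 8.17 to 52.2 with a median of 10.7. Of 21631 protein-coding genes, 3894 (18.0%) had a peak near an end. Of the tested genes with a position, 3830 (26.0%) had 1.

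The peak of highest score lay on chromosome 3 at 54690771 to 54693863 (3093 bp, score 52.2), at the low-coordinate end of Supt20, encoding a subunit of the SAGA coactivator. The next lay at the ends of Cep57 and Fam76b (chromosome 9, 13825758 to 13828396, score 50.1). The third lay at an end of Asf1a, encoding a histone chaperone, and overlapped Mcm9 (chromosome 10, 53596727 to 53598686, score 46.2), and the fourth inside Gnas, an imprinted locus (chromosome 2, 174295461 to 174299450, score 46.0). Peaks near ends of Tbc1d2 (42.2), Cramp1l and Ift140 (41.6), Bcl2l12 and Irf3 (40.3), L3mbtl3 (37.5) and Rcc2 (36.2) and a peak away from protein-coding genes (chromosome 6, 117879249 to 117880928, score 38.5) completed the 10 highest. L3mbtl3 encodes another MBT-domain reader.

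Ctnnb1 and Gabra2 each had a peak. That of Ctnnb1 covered its low-coordinate end (chromosome 9, 120933101 to 120933617, 517 bp, score 14.0). That of Gabra2 lay just inside its high-coordinate end (chromosome 5, 71094652 to 71095541, 890 bp, score 8.68). No peak lay within 2000 bp of an end of L3mbtl1. In total 23 of the 110 named genes with a position had a peak, among them Fos with 3 peaks (scores 9.34, 8.71 and 11.8), Fosb (13.1), Fosl2 (23.1), Sdf2l1 (11.1), Grin3a (10.7), Gria4 (9.4), Sfmbt1 (13.1) and Fdps (22.4 and 16.2). Among the gene lists, 13 of 22 immediate early genes (59.1%) had a peak near an end, against 26.0% of other tested genes (Fisher's exact test, 2-sided, odds ratio 4.12, p = 0.00104, adjusted p = 0.0312 over 30 lists). It was the only list past 0.05 of the 30 tested for peaks, a test added after the data were examined. The lists were not compared within bins of expression. Among autosomal coding genes the share with a peak was 8.27% in the lowest of 10 expression bins and 37.4% in the highest.

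**Figure D3:**
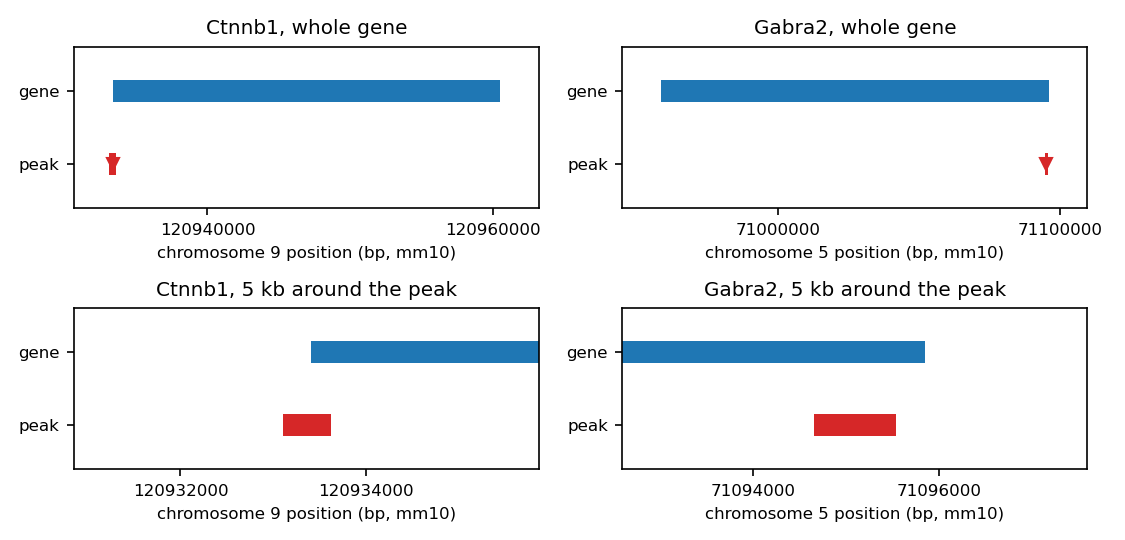
Position of the L3mbtl1 peak (red) and the annotated gene (blue) at Ctnnb1 on chromosome 9 and Gabra2 on chromosome 5, in bp of mm10, for the whole gene (top, peak marked by a triangle) and for 5 kb around the peak (bottom). The Ctnnb1 peak covers the low-coordinate end at 120933400 and the Gabra2 peak ends at 71095541, inside the gene end at 71095849.

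Genes that rose under picrotoxin carried peaks more often than genes that were not called. The calls were those of the fit without pairing. The replicate block called more genes (8820 against 6248), and the peak test was not run on its calls. A peak lay near an end of 873 of 2910 genes that rose (30.0%), 801 of 3051 that fell (26.3%) and 2156 of 8768 that were not called (24.6%). Fisher's exact test (2-sided) gave an odds ratio of 1.31 (95% interval 1.2 to 1.44, p = 1.1e-08, adjusted p = 3.3e-08) for genes that rose, 1.09 (0.99 to 1.2, p = 0.0688) for genes that fell and 1.2 (1.11 to 1.29, p = 2.28e-06, adjusted p = 3.41e-06) for both together. Genes with a peak were expressed more highly, with a median of 5.26 log2 CPM against 4.2 without. Compared within 10 bins of mean expression, the odds ratio for genes that rose was 1.1 (1.0 to 1.21, logistic regression p = 0.0483, adjusted p = 0.145, n = 2910 and 8768 genes). For all changed genes it was 1.03 (0.95 to 1.11, logistic regression p = 0.493, n = 5961 and 8768 genes), so that this call was lost. By size of change, 35.1% of genes that rose less than 2-fold and 28.6% of those that fell less than 2-fold had a peak. Among those that rose or fell at least 2-fold the shares were 20.4% and 19.0%, below the 24.6% of genes not called. These classes also differed in expression, with medians of 5.62, 5.16, 3.83 and 3.43 log2 CPM, and 4.09 for genes not called. The shares are not adjusted for this.

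**Figure D4:**
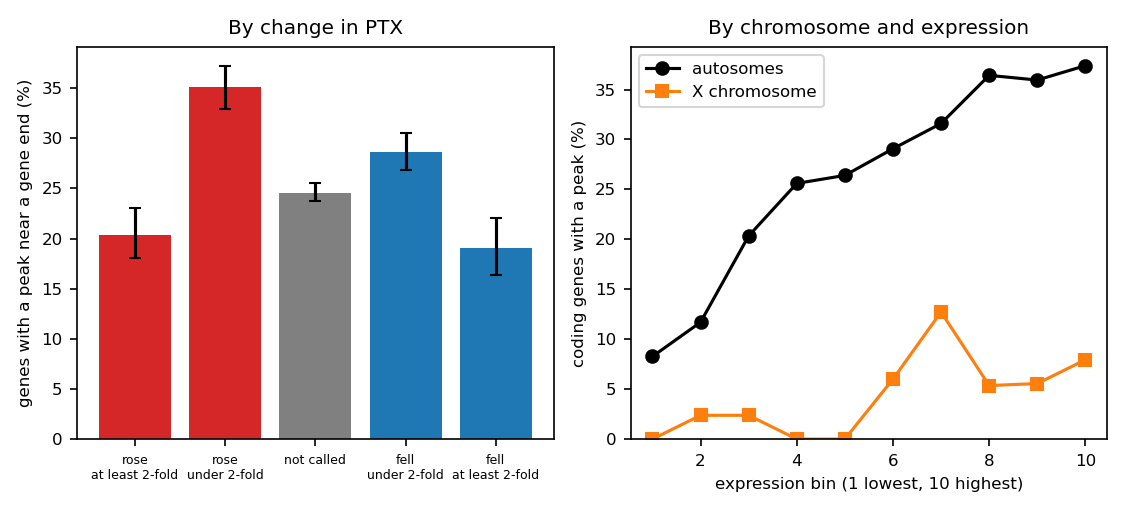
Left, percent of tested genes with a peak near a gene end by their change in PTX (bars from 0, Wilson 95% intervals), highest for genes that rose under 2-fold (35.1%). Right, percent of coding genes with a peak in 10 bins of mean expression (1 lowest), which is lower on the X chromosome than on autosomes in each bin.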

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

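Of the tests of explanations below, those on skin cells, gene copies and expression level were chosen only after the results were seen, and that on the X copy number after the low share on X was seen but before the share it is compared with was computed. The gap of 1 library from the other 3 of its group, as a share of the group's range, was above Dixon's 95% critical value in 15 of 296 groups of 4 libraries (named genes, library measures and list medians). Chance flags about 1 in 20 groups, or 14.8 here, so the number is about that of chance, but 12 of the 15 fell on the 2 libraries numbered 1.

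CTRL replicate 1 was low in Cnp (16.6 CPM, others 27.7 to 29.5), Cd68 (3.6 CPM, others 11.4 to 11.8), P2ry12 (0.47 CPM) and Aif1 (0.35 CPM), and high in Slc6a13 (40.6 CPM, others 2.29 to 5.74). Its microglia markers had a median of -1.84 in log2 CPM relative to all libraries, against 0.29 to 0.61 in the other CTRL libraries. PTX replicate 1 was high in Slc6a13 (23.7 CPM), Fdps (93.2 CPM) and Grin2d (1.53 CPM). Its list medians were 0.15 for vesicle release, 0.11 for calcium channels and -0.80 for oligodendrocyte precursors, against -0.18 to -0.13, -0.38 to -0.31 and 0.37 to 0.52 in the other PTX libraries. The rest were Tet3 (33.1 CPM) and Fn1 (34.2 CPM) in CTRL replicate 2 and Cacna1d (17.9 CPM) in PTX replicate 4. Without both libraries numbered 1 the comparison called 6042 genes.

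Skin barrier genes (Krt6a, Lce1g, Lce3c, Crct1) were among the largest rises in all 4 PTX libraries. Skin cells in the PTX cultures would bring their other abundant transcripts. The 10 keratinocyte genes were Krt5, Krt14, Krt15, Krt1, Krt10, Krt16, Krt17, Trp63, Col17a1 and Dsg1a. Their highest PTX mean was 0.827 CPM, for Krt1, against 276.9 CPM for Krt6a. This argues against skin cells as the source, but the list was written after its counts had been seen. Krt5 went from 0 counts in CTRL to 35 in PTX and Krt16 from 0 to 5. The others had counts in CTRL too. Of these, Krt17, Col17a1 and Dsg1a had more counts in PTX, and Krt14, Krt15, Krt1, Krt10 and Trp63 fewer. Reads moving between gene copies would leave family sums level, but the summed counts of the Krt6, Lce and Ifi2 families were 1070-fold, 714-fold and 9.91-fold higher in PTX, which argues against it too. Induction in the cultured cells under picrotoxin stays open as a hypothesis.

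Genes that rose had L3mbtl1 peaks more often than genes not called (24.6%). This held for rises under 2-fold (35.1%) and not for rises of at least 2-fold (20.4%). Peak genes were more highly expressed, and higher counts make calls easier, so expression level may account for the excess. For all changed genes the odds ratio went from 1.2 to 1.03 within expression bins, as this explanation requires. For genes that rose it went from 1.31 to 1.1, with an interval whose low bound is 1.0 and an adjusted p of 0.145, which leaves open whether any excess remains.

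Peaks were rare on the X chromosome. Of 489 tested coding genes on X, 23 (4.7%, Wilson 95% interval 3.15% to 6.96%) had a peak near an end, against 27.3% of 13167 autosomal genes. Lower expression of X genes does not account for this, since the odds ratio within 10 expression bins was 0.123 (95% interval 0.0808 to 0.188). A candidate explanation is that the X is present in 1 copy in males, which would give about 50% of the autosomal signal. The share of autosomal genes with a peak of at least 2 times the lowest score was 4.03%, within the interval of the X share. Of the 489 X genes, 5 had such a peak, a count the test did not use. That test takes the score as proportional to signal, which is not given in the sources used here, and the sex of the ChIP-seq mice was not used, so a biological difference between X and autosomes also remains open, untested.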

How the results depend on the processing

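Leaving out both libraries numbered 1 or 2, the block with an estimated correlation, and the splits were chosen only after the results were seen. The count of 6248 genes stayed within 1.5 times under all alternatives run, from 5119 without CTRL replicate 3 to 8820 with the replicate block, and of genes called in both fits 0 changed sign. The block lost 1 of the 6248 calls. It changed the camera call of 0 of the 31 lists and no call of a named gene beyond those given with the results, but it called further members of several lists, whose block counts are given only where they moved by over 1.5 times. Leaving out both libraries numbered 2 gave 5540 genes. L3mbtl1 stayed lower and past the threshold in all fits, with edgeR adjusted p up to 0.0101 (without PTX replicate 4). Of 115 named genes, 100 kept their side of the threshold without each library in turn. The 15 others were Gabra2, Grin2d, Grin2b, Fdps, mt-Nd1, mt-Nd2, mt-Atp8, Rps3, Cnp, Cldn11, Vcan, Olig2, Ogn, Aurka and Mcm2. Grin2b and mt-Atp8 also lost the call with RLE scaling, mt-Atp8 with DESeq2, and Aurka and Mcm2 without the filter. Without both libraries numbered 1 the calls of mt-Nd1, mt-Nd2 and Aurka were lost and Gabra2, Cnp, Cldn11, Olig2 and Gpr17 passed, and without both numbered 2 the calls of Fdps, mt-Atp8 and Mcm2 were lost.

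Lists past camera numbered 11 to 14 under other scaling, filter, voom, block and single libraries left out, but 1 with an estimated correlation and 0 with that and the block, so list calls depend on the assumed correlation. Voom added calls of the AMPA auxiliary (camera adjusted p = 0.0287), mitochondrial (0.046, range 0.0365 to 0.71) and ribosomal (0.046, range 0.046 to 0.916) lists, and no filter those of the first 2. Voom did not call the metabotropic receptors (camera adjusted p = 0.111, range 0.000528 to 0.451) or scaling regulators (0.0999, range 0.00029 to 0.552), and both libraries numbered 1 left out ended the call of glycolysis (0.0629, range over alternatives 0.00268 to 0.648) and added that of the AMPA auxiliary list. As large a number of genes came from 1 of 35 splits, the real one (6248, highest other 5). That is the smallest share these splits can give, and only 8 of them part all 4 pairs. Every other split also puts CTRL and PTX libraries on the same side. The PTX difference then adds to the spread within its groups and lowers its count of genes, so these counts do not measure chance alone. For camera lists 8 of 35 splits reached the real 12 (highest other 23, CTRL replicates 1, 2 and 3 with PTX replicate 1), so chance is not excluded. Of the 7 others, 5 keep 3 of 4 libraries on their own side and so carry part of the PTX difference, and 2 hold 2 CTRL and 2 PTX libraries on each side and gave up to 14 lists. Among the 8 splits that part all 4 pairs, the highest others were 0 genes and 11 lists, but 8 splits are too few for a share under 0.05. fry, counted on the same splits after the data were examined, gave 20 lists in the real split and 0 in all others. Since fry does not compare a list with other genes, and the other splits called at most 5 genes, this shows nothing particular to these lists.

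The share of peaks near a gene end was 79.2% at 1000 bp, 89.9% at 5000 bp, 82.9% by peak centre and 87.0% for the peaks of higher score, as the window and peaks differ. The odds ratio of peaks among changed genes was no longer past 0.05 with the peaks of higher score (1.09, Fisher's exact p = 0.0665) or within expression bins (1.03), and that of genes that fell passed with 5000 bp windows (1.1, Fisher's exact p = 0.0428). For changed genes, expression level as a cause was tested above. The causes of the other differences were not tested. With 4 libraries a group, simulated 1.5-fold changes were recovered in 32.8% of genes. The simulation gave 149 calls over 15871 genes, against 6248 of 15959 in the real comparison. Its adjusted threshold was therefore stricter, and the 32.8% does not carry over to the real comparison, where small changes can still be missed.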

Other observations

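The genes and regions below were chosen after their values were seen, whereas the test of neighbouring genes was set down before its result. A run of gene models on chromosome 14 (mm10, 3571683 to 7488882) rose together. Of 25 tested there, 24 rose and 0 fell, 14 of them at least 8-fold, with 1456 counts over CTRL and 11732 over PTX libraries in the 24. All 24 are unnamed models (Gm or Rik), among them 2610042L04Rik, Gm3629 and Gm3636, and near-identical copies make the assignment of reads to each uncertain.

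Nefl rose 10.4-fold from 319.3 ± 119.3 to 3318 ± 777.2 CPM (SD, n = 4, edgeR adjusted p = 1.42e-05) and Nefm 16.3-fold, whereas Nefh (14.2 ± 6.31 and 14.5 ± 6.04 CPM, adjusted p = 0.956) did not pass. Areg, an EGF receptor ligand, rose 86.9-fold from 0.38 ± 0.15 to 33.0 ± 5.75 CPM, the cytokine gene Il1a 16.6-fold, Il1b 10.9-fold (9 and 95 counts) and the protease gene Mmp10 155.3-fold (9 and 1322 counts), while Cxcl1 (adjusted p = 0.877) and Ccl2 (adjusted p = 0.265) did not pass.

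Xist, transcribed from the inactive X, had 7322 and 6006 counts in CTRL and PTX replicate 2 and 4 to 13 in the other 6 libraries. The Y-linked Ddx3y had 7 and 5 counts in those 2 libraries and 3459 to 8177 in the others.

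A hypothesis was tested that neighbouring genes rise together. Of 175 genes with positions that rose at least 8-fold, 27 had another such gene of a different name stem within 500 kb, against a median of 23 in 1000 random sets of tested genes of like expression (permutation p = 0.31), so an excess beyond chance was not shown, nor is it excluded, since 27 lies above the median and below the upper bound of 37 of the central 95% of random sets.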
